A study of Mus musculus with 2 samples.

How the data were processed

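Small RNA was measured by microRNA sequencing in 2 libraries of mouse liver at embryonic day 15.5. Each library was made from total RNA of a pool of embryos of both sexes, of the strain B6NCrl, a C57BL/6N stock. The first pool held 78 embryos and the second 62, and the submitters number them as biological replicates 1 and 2. Per the labels, RNA of under 30 nucleotides was selected. The labels give 1 group, fetal liver, so no comparison between conditions could be made, and a pool averages its embryos, so the spread between the libraries measures pools and library making, not single animals.

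The deposited tables hold whole-number read counts per annotated miRNA gene, 1 table per library, with no normalization. Per the text deposited beside the tables, counting used the mouse assembly mm10 (GRCm38) and annotation release M4. The aligner, the counting program and adapter trimming are not given in the sources used here. The deposited tables give 3 count columns, for both strands together, the gene's own strand (sense) and the opposite strand, and for every gene the last 2 summed to the first. They also give the reads assigned to no gene. In replicate 1, 23.9% of 14666947 reads were unmapped, 29.3% mapped to several places and 5.40% lay outside the annotated genes. In replicate 2 these were 21.4%, 31.1% and 6.23% of 8454226 reads. Ambiguous reads were 0 in both. None of these reads entered a library size or test. Reads that map to several places were left out of the gene counts, which lowers miRNAs whose mature sequence is the same at several loci.

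Sense counts were the basis of the main results, since ligated adapters keep the strand of a small RNA. They summed to 5529166 in replicate 1 and 3169882 in replicate 2, a ratio of 1.74. CPM divides a gene's counts by the library's sense miRNA counts and multiplies by 1000000. Where opposite-strand counts were given to the overlapping miRNA gene, CPM and ranks use totals that include them, 6060372 and 3487829. Names and positions came from annotation release M21 on the same assembly. Of 1973 gene identifiers, 1894 matched by their stable part, and 79 of these carried another version number, so their positions may differ from those used in counting. The 79 unmatched identifiers had at most 1 sense count. Host genes, exons and introns are as in release M21. The counts are of precursor genes and do not separate the arms of a precursor.

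A gene was called detected with at least 10 counts in both libraries. Correlations across genes used log2(CPM + 1). TMM scaling and the common dispersion came from edgeR 4.0.16 in R 4.3.3, with an intercept only, and DESeq2 1.42.0 gave alternative size factors. The libraries were compared gene by gene with a two-sided exact conditional binomial test on genes with at least 10 counts summed, with the expected share set by TMM-scaled sizes, Benjamini-Hochberg adjustment and a threshold of 0.05. That test covers counting error only and compares the 2 libraries, not conditions. Log2 ratios are replicate 2 over replicate 1, on TMM-scaled sizes. A chi-square over genes also asked whether both tables could be 1 library deposited more than once. Shares of counts in a single library carry exact Clopper-Pearson 95% intervals. Values after ± are SDs of 2 libraries, which can be smaller than counting error where both values happen to coincide. Sequencing reads amplified by PCR without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. A count of 0 allows up to 3 counts, or 0.543 CPM in replicate 1 and 0.946 CPM in replicate 2.

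The 19 miRNA lists were fixed before the data were examined, as were the tests and most alternatives. They cover cell types of fetal liver (hepatocyte, erythroid, leukocyte, haematopoietic progenitor, endothelial, mesenchymal), other tissues as controls (muscle, neural, pancreas, epithelial, pluripotent, X-linked germline), imprinted loci and families or clusters (Dlk1-Dio3, Igf2-H19, Sfmbt2, let-7, miR-17 clusters, miR-15/16), and miRNAs whose mature sequence is known from several loci (multicopy). Each list's median level was set against 10000 random lists of the same size from all annotated miRNA genes, and its median log2 ratio against 10000 random lists matched on mean expression. Both percentiles describe these libraries and are not p-values. Levels of adjacent miRNA genes on the same strand within 10 kb were compared with shuffled levels in a two-sided permutation test of 100000 resamples. Genes were named by a fixed rule: the 20 highest by mean CPM, the 3 highest of each list, and the 5 largest log2 ratios in each direction among genes with a mean of at least 100 CPM. Other genes are named as members of a cluster, list or locus, or because their values stood out once seen.

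The steps were tested on simulated data. For the binomial test on 456 genes, 5 of 256 unchanged genes were called, and 64.8% of 71 genes changed 1.5-fold, 62.1% of 66 changed 2-fold and 92.1% of 63 changed 4-fold were recovered. These counts were drawn with Poisson error only. The rates therefore do not describe calls under the wider spread between real pools. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used. Alternatives covered strand, count minimum, scaling, pseudocount, leaving out a library, the denominator, the random lists and the distance between neighbours. An alternative that gives opposite-strand counts to the overlapping miRNA gene was chosen after seeing the data, as was 1 that leaves out Mir451a.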

Results

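The data are miRNA gene counts from fetal mouse liver at embryonic day 15.5, a stage at which the liver is also the main site of blood formation. There was 1 group of 2 libraries, each from a separate pool of embryos. Sense miRNA counts were 5529166 in replicate 1 and 3169882 in replicate 2. Of the 1973 annotated miRNA genes in the deposited tables, 645 had at least 1 sense count in replicate 1 and 605 in replicate 2. Some known miRNA genes, Mir142 and Mir409 among them, are not among the 1973. With at least 10 counts, 406 genes were detected in replicate 1, 362 in replicate 2 and 352 in both. Replicate 1 was the deeper library. When it was thinned to the depth of replicate 2, a median of 358 genes reached 10 counts (range 353 to 367 over 100 draws), close to the number in replicate 2. The design asks which miRNAs make up the fetal liver and how closely separate pools match.

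A single miRNA gene led the profile. Mir122, which encodes the most abundant miRNA of hepatocytes, took 17.6% ± 0.961 of sense counts (SD, n = 2). It was 18.2% in replicate 1 (exact 95% interval 18.2 to 18.3) and 16.9% in replicate 2 (16.8 to 16.9). The gene (ENSMUSG00000065402.1) lies on chromosome 18 at 65248861 to 65248926, GRCm38, in an exon of the long noncoding RNA AC157910.3. Its level of 175539 ± 9614 CPM was 3.18 ± 0.347 times that of the next gene, Mirlet7g, at 55446 ± 3032 CPM. The 10 most abundant genes together held 48.4% ± 0.366 of counts and the 20 most abundant 65.2% ± 0.221.

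Several of the genes that followed lie in known cell type, proliferation or imprinted loci. Mir126a, the endothelial miRNA of Egfl7 (chromosome 2, 26591357 to 26591429), stood at 44199 ± 867 CPM. Mir26b, in an intron of Ctdsp1, stood at 43398 ± 1028 CPM. Mir335, in an intron of the imprinted gene Mest (chromosome 6, 30741299 to 30741396), stood at 37680 ± 5355 CPM. Mir17, the first gene of the miR-17-92 cluster in Mir17hg, stood at 32610 ± 1368 CPM, and Mir411 of the imprinted Dlk1-Dio3 domain at 26893 ± 753 CPM. Mirlet7i, Mir322 and Mir21a completed the first 10 by sense counts at 24990 ± 2199, 22429 ± 2237 and 20891 ± 330 CPM. With opposite-strand counts given to the overlapping miRNA genes, and CPM taken over totals that include them, Mir142 would rank 5 at 34828 CPM, above Mir335 at 34305 on that scale, and Mir409 would rank 9. The next were Mir223, a miRNA of granulocytes and their precursors, at 18838 ± 901 CPM, Mir127 at 18479 ± 712 CPM, Mir30e at 18411 ± 496 CPM and Mir130a at 17155 ± 163 CPM. Mir487b, Mir30a, Mir99a, Mir143, Mir93 and Mir20a lay between 17084 and 14842 CPM.

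Among the cell type lists, the hepatocyte list was the largest, with 18.8% ± 1.04 of counts over 7 measured members. Without Mir122 it held 1.54% of the remaining counts. Its other leading members were Mir101b at 6582 ± 409 CPM and Mir192, a miRNA of liver and gut, at 3298 ± 222 CPM. The endothelial list, represented by Mir126a alone, held 4.42% ± 0.0867. The haematopoietic progenitor list held 2.50% ± 0.0288, led by Mir130a, Mir99b at 6253 ± 152 CPM and Mir125a at 1131 ± 17.5 CPM. The erythroid list held 2.29% ± 0.606. Its 3 measured members were Mir451a at 13751 ± 6940 CPM, its neighbour Mir144 at 8347 ± 807 CPM, and Mir486, in an intron of the erythrocyte ankyrin gene Ank1, at 766 ± 73.4 CPM. Mir486 overlaps Mir3107 on the other strand, where 347 and 203 counts lay in replicates 1 and 2. Any reads that map to both were left out, so the level of Mir486 is uncertain. The mesenchymal list, led by Mir143, Mir140 (4111 ± 565 CPM) and Mir214 (866 ± 95.8 CPM), held 2.10% ± 0.0569. The leukocyte list held 2.04% ± 0.103. Mir223 made up most of it, followed by Mir342 at 1121 ± 106 CPM and Mir146 at 319 ± 20.7 CPM. With opposite-strand counts given to the overlapping miRNA genes, which adds Mir142, the leukocyte list came to 5.34%. The ratio of the hepatocyte to the erythroid list was 7.21 in replicate 1 and 9.74 in replicate 2, and it was 0.572 with Mir122 left out.

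**Figure D1:**
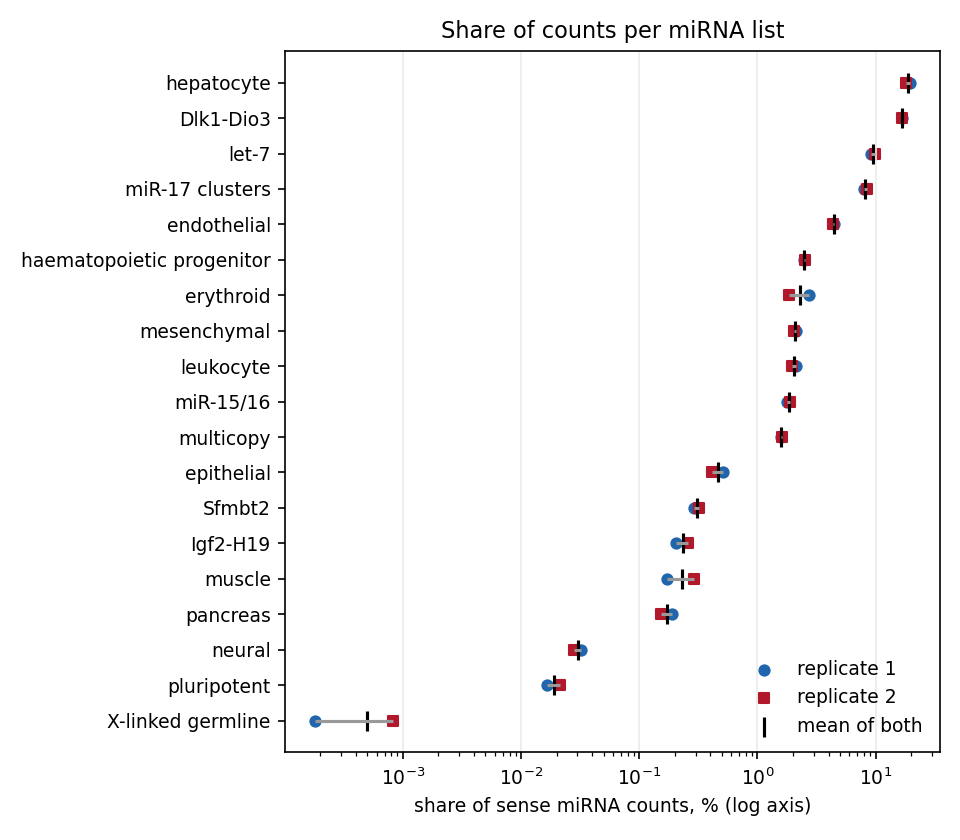
Share of sense miRNA counts (%, log axis) taken by each of the 19 lists. Circles are replicate 1, squares replicate 2 and ticks their mean. The hepatocyte list leads at a mean of 18.8% and the X-linked germline list is lowest at 0.000501%.

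Lists of other tissues were low but most were above the detection minimum. The epithelial list held 0.462% ± 0.0746 with 9 of 9 measured members detected, led by Mir429 at 2343 ± 384 CPM and Mir200b at 705 ± 98.0 CPM. The muscle list held 0.231% ± 0.0827, nearly all from Mir206, a skeletal muscle miRNA, at 2029 ± 847 CPM. Its members Mir1a-1, Mir133a-1 and Mir133a-2 are also on the multicopy list. Their reads can be lost as mapping to several places, so the muscle share and the lead of Mir206 are uncertain. Mir499 and Mir208b, in introns of the myosin genes Myh7b and Myh7, stood at 183 ± 11.9 and 71.3 ± 15.2 CPM. The pancreas list held 0.172% ± 0.0267, from Mir375, a miRNA of pancreatic islets and gut endocrine cells, at 1703 ± 266 CPM. Mir217 and Mir216b were at 9.10 and 3.34 CPM. The neural list held 0.0301% ± 0.00278, with Mir128-1 at 124 ± 4.31 CPM and Mir137 at 49.8 ± 23.6 CPM. Most of it came from genes also on the multicopy list, and without these it held 0.00591%. Reads of those genes can be lost in the same way, so the neural share can be too low. The pluripotent list held 0.0189% ± 0.00335, with Mir293 at 53.4 ± 18.5 CPM. In the X-linked germline list, 0 of 15 members were detected. That list had 10 counts in replicate 1 and 26 in replicate 2. The median level of 14 of the 17 lists with at least 3 measured members lay above the 97.5th percentile of random lists of annotated miRNA genes. The exceptions were the pancreas (92.6), Sfmbt2 (49.9 in replicate 1) and X-linked germline (46.7) lists. The bound was easily passed, since 1328 of 1973 annotated genes in replicate 1 and 1368 in replicate 2 had 0 sense counts. With detected members set against random lists of detected genes only, 4 lists lay above it: hepatocyte (97.6), erythroid (97.8), Dlk1-Dio3 (100) and let-7 (98.3). The miR-15/16 (96.9) and haematopoietic progenitor (96.7) lists lay just below the bound, so the split is not sharp. The muscle, neural and pluripotent lists then lay at percentiles 37.25, 12.6 and 8.69.

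Imprinted loci carried a large share. The Dlk1-Dio3 list, maternally expressed miRNAs on distal chromosome 12, held 16.7% ± 0.00369 of counts, with 45 of 48 measured members detected. Its exact 95% interval was 16.66 to 16.72% in replicate 1 and 16.64 to 16.72% in replicate 2, wider than that SD. The list came to 19.1% with opposite-strand counts given to the overlapping genes. By sense counts its 3 highest members were Mir411, Mir127 and Mir487b, while with counts reassigned Mir409 would lie between Mir411 and Mir127. A run of 34 genes on the plus strand from 109709060 to 109747960, which includes Mir411 and Mir487b, held 11.6% ± 0.00246, with 30 genes detected. A second run of 13 genes from 109563692 to 109595030, antisense to Rtl1 at Mir127, held 4.64% ± 0.0268. At Igf2-H19 the list held 0.234% ± 0.0386, with Mir483, in an intron of Igf2, at 2191 ± 372 CPM and Mir675, in an exon of H19, at 134 CPM in replicate 1 and 154 CPM in replicate 2. The Sfmbt2 list holds gene families of a rodent cluster with many near-identical copies. Of its 69 members 59 lie in Sfmbt2, and the 10 elsewhere had 0 sense counts. Of the 69, 9 were detected, led by Mir467c at 956 ± 71.7 CPM. Mir467d stood at 797 CPM in replicate 1 and 803 CPM in replicate 2, and Mir467e at 701 ± 95.3 CPM. Their counts are uncertain because reads shared by copies were left out.

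**Figure D2:**
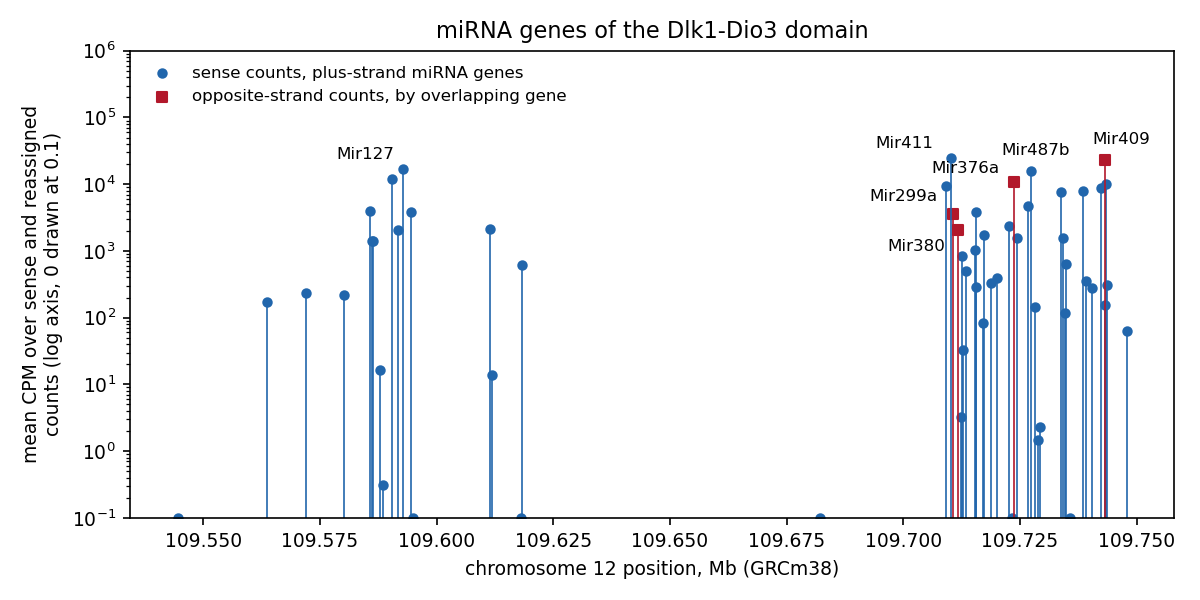
Mean CPM of both libraries (log axis) of miRNA genes by position on chromosome 12 (Mb, GRCm38), for all marks over totals that include reassigned opposite-strand counts. Circles are sense counts of plus-strand genes, and squares are opposite-strand counts drawn at the overlapping gene, such as Mir409 at 22900 CPM. Genes at 0 are drawn at 0.1.

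The let-7 list held 9.56% ± 0.526, led by Mirlet7g (chromosome 9, 106178840 to 106178927, in an intron of Wdr82), Mirlet7i and Mirlet7d (7180 ± 42.7 CPM). Without its members on the multicopy list it held 9.30%. Reads of those members can be lost as mapping to several places, so the let-7 share and the order of its members are uncertain. The miR-17 clusters, which are proliferation-linked, held 8.19% ± 0.376. Of this, the 6 genes of chromosome 14 at 115043671 to 115044506 held 5.71% ± 0.296, and the 3 genes in Mcm7 on chromosome 5, led by Mir93, held 2.41% ± 0.0740. The miR-15/16 list held 1.84% ± 0.0752, led by Mir15a at 9918 ± 492 CPM, Mir16-1 at 4885 ± 265 CPM and Mir15b at 2619 ± 0.291 CPM. The multicopy list, whose reads can be lost as mapping to several places, held 1.59% ± 0.0346. Its highest members were Mir16-1, Mir92-1 (4271 ± 230 CPM) and Mirlet7f-2 (2021 ± 20.5 CPM).

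Neighbouring miRNA genes were compared because clusters are often made from 1 transcript. Over 310 adjacent pairs, the mean absolute difference in log2 level was 2.10, against 2.50 after shuffling, which did not pass the threshold (permutation test, two-sided, p = 0.0960). Over 113 pairs of detected genes it was 3.45 against 4.22 (permutation p = 0.00576). It also passed with unstranded counts (permutation p = 0.0481), for pairs within 50 kb (permutation p = 0.0238) and with opposite-strand counts reassigned (permutation p = 0.0438). It did not pass within 1 kb (permutation p = 0.301), without the Sfmbt2 list (permutation p = 0.129), or in either library alone (permutation p = 0.0906 and 0.106). These tests are across genes, which are not independent replicates.

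The pools matched closely in most genes. Across 352 detected genes Pearson r was 0.994 and Spearman rho 0.991, on log2(CPM + 1). Genes are not independent replicates, so no p is given. The biological coefficient of variation from edgeR was 12.9%. Of 187 genes with a mean of at least 100 CPM, 183 lay within 1.5-fold and 1, Mir451a, was at least 2-fold apart. The libraries were not the same library deposited again: the chi-square per degree of freedom over genes was 68.6 with 455 degrees of freedom. At this depth small differences pass a test of counting error. Of 456 genes tested, 178 differed by the exact binomial test, 83 higher and 95 lower in replicate 2, and 200 had an unadjusted p under 0.05. The balance depends on scaling: by total counts 97 were higher and 80 lower, and by DESeq2 size factors 86 and 89. Of the 178, 39 were at least 2-fold apart, 20 higher and 19 lower.

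**Figure D3:**
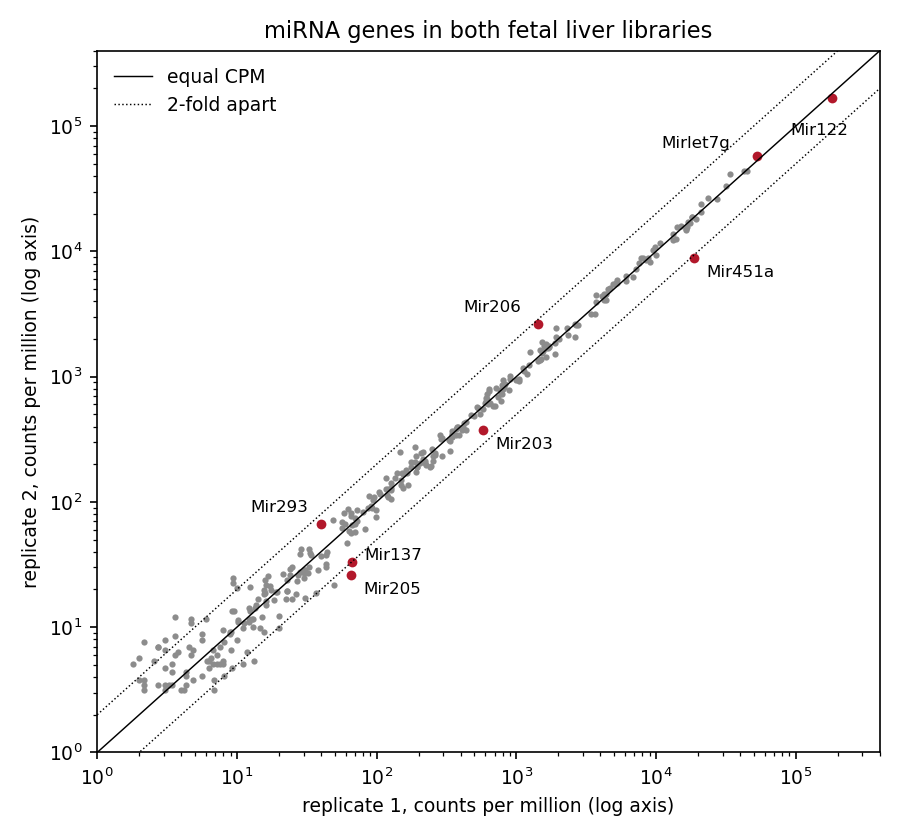
CPM of 352 detected miRNA genes in replicate 1 (x) and replicate 2 (y), both log axes. The solid line marks equal CPM and dotted lines mark 2-fold. Mir451a lies furthest from the line among genes of at least 100 CPM, at 18658 CPM in replicate 1 and 8843 CPM in replicate 2.

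Mir451a (chromosome 11, 78073170 to 78073241), a red cell miRNA cut by Ago2 rather than Dicer, was 2.16-fold lower in replicate 2, a log2 ratio of -1.11. Mir144, on the same strand and upstream of it at 78073005 to 78073070, was higher in replicate 2, with a log2 ratio of 0.16 (exact binomial test, Benjamini-Hochberg adjusted p = 1.61e-46). That ratio is below the SD of 0.187 of the log2 ratios of genes with at least 100 CPM other than Mir451a. Mir451a counts were 2.40 times those of Mir144 in replicate 1 and 0.992 times in replicate 2. The other genes furthest lower in replicate 2 were Mir203 (-0.66), Mir182 (-0.45), Mir145a (-0.39) and Mir181b-2 (-0.38), as log2 ratios. The 5 furthest higher were Mir206 (0.84), Gm23935 (0.75), Mir6236 (0.52), Mir700 (0.36) and Mir483 (0.31). All of these 10 genes passed the exact binomial test.

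By list, the epithelial miRNAs moved together. All 9 detected members had lower ratios, and 8 of them were lower in replicate 2 past the threshold over all genes tested, while 9 were when adjusted over the list alone. Their median log2 ratio was -0.37, at percentile 0.01 of matched random lists. Examples were Mir429 (-0.37), Mir200b (-0.32) and Mir203. Mir429, Mir200a and Mir200b lie in 1 cluster, and Mir141 and Mir200c in another. The 9 members are therefore not independent loci. Random lists drew genes singly, so clustered members can make the percentile too extreme. In the hepatocyte list 7 of 7 members tested were lower in replicate 2, and 7 when adjusted over the list alone, with a median of -0.17 at percentile 0.94. Mir122 was at -0.15. In the pluripotent list 3 of 10 tested were higher in replicate 2 and 0 lower, and 3 when adjusted over the list alone, with a median of 0.40 at percentile 98.2, though its highest member had 53.4 CPM. The pluripotent members lie in a cluster of 7 genes on chromosome 7 and a cluster of 5 on chromosome 3. They are not independent loci either, so this percentile can also be too extreme. The erythroid list had 2 members higher and 1 lower, and 3 changed when adjusted over the list alone. Its median log2 ratio was 0.16, at percentile 99.2, while its mean was -0.26 and its share was 2.71% in replicate 1 and 1.86% in replicate 2, of which Mir451a alone was 1.87% and 0.884%. The erythroid list lay inside the bounds with unstranded counts (percentile 97.1), with opposite-strand counts reassigned (84.0) and against random lists not matched on expression (84.5), and the hepatocyte list against unmatched lists (9.73). The pluripotent list lay inside them with no count minimum (97.3) and with a minimum of 50 counts (88.3).

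The other lists with at least 3 detected members lay within the random bounds at the minimum of 10 counts. With a minimum of 50 counts the muscle list lay at percentile 98.1, against 13.0, and with no count minimum the neural list at 0.08, against 55.2. The X-linked germline list, which had too few detected members at the minimum of 10, lay at 99.9 with no count minimum. In the muscle list 2 of 6 members tested were higher in replicate 2, Mir206 among them, and 2 lower, with Mir208b at -0.47, and 5 changed when adjusted over the list alone. Its share was higher in replicate 2, and the median of -0.17 and the mean of 0.12 differ in sign. Over all genes, 178 of 456 tested differed, and 116 of the 187 with a mean of at least 100 CPM did. Counts within a list that are near these rates are not particular to that list. The miR-17 clusters had 8 members higher and 1 lower of 15 tested, and 9 changed when adjusted over the list alone. For the Dlk1-Dio3 list these were 10 and 13 of 46 tested, and 23 when adjusted over the list alone, with a median of 0.00123. The let-7 list had 2 higher and 4 lower of 10 tested, and 6 changed when adjusted over the list alone. Its share was higher in replicate 2 while its median was -0.09. The leukocyte list had 4 of 6 tested lower, and the haematopoietic progenitor list had 0 of 4 tested changed by the exact binomial test and 2 with an unadjusted p under 0.05, with the same counts adjusted over the list alone. Members higher and lower were 2 and 2 of 7 tested in the mesenchymal list, 0 and 4 of 11 in the neural list, 2 and 0 of 5 in the miR-15/16 list, 2 and 1 of 10 in the Sfmbt2 list and 5 and 9 of 42 in the multicopy list, again with the same totals adjusted over the list alone. Mir375 (-0.36) was the 1 pancreas member that differed of 4 tested, and Mir126a (-0.08) and Mir483 differed in the endothelial and Igf2-H19 lists. In the X-linked germline list 1 gene, Mir741, was tested, and it passed only when adjusted over the list alone.

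**Figure D4:**
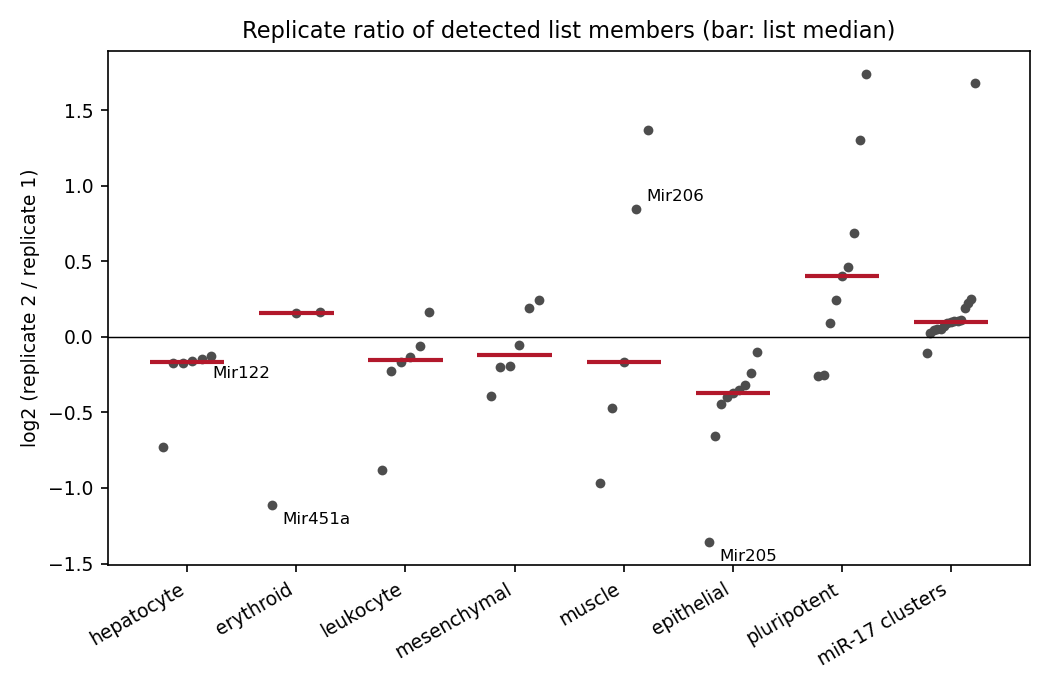
Log2 ratio of replicate 2 to replicate 1 (TMM-scaled) of the detected members of 8 lists, 1 point per gene, with the list median as a bar. All 9 epithelial members lie below 0, and Mir451a lies at -1.11 apart from the other erythroid members at 0.16.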

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

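All tests of explanations here were chosen after the results were seen. Both libraries hold reads outside the sense counts used in the report. On the strand opposite to an annotated miRNA gene lay 8.77% of assigned reads in replicate 1 and 9.12% in replicate 2. Reads that map to several places were 29.3% and 31.1% of all reads, and reads outside the annotated genes 5.40% and 6.23%. The main values in the report rest on none of them.

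The opposite-strand reads sat in a few places. In 10 genes the opposite strand had at least 100 counts in both libraries and more than the sense strand. Each overlaps a well-known miRNA gene of release M21 on the other strand whose identifier is not among the 1973 in the deposited tables. Counted as those genes, over totals that include the reassigned counts, the levels were 34828 CPM for Mir142 (at Mir142b), the blood cell miRNA, which would rank 5, 22900 for Mir409 (at Gm24321), 10890 for Mir376a (at Gm25252), 7791 for Mir378a (at Gm25301) and 4636 for Mir191 (at Gm24083). They were 3597 CPM for Mir299a (at Mir299b), 2279 for Mirlet7e (at Gm25927), 2064 for Mir380 (at Gm25750), 193 for Mir497 (at Mir497b) and 90.6 for Mirlet7f-1 (at Gm24111). Mir142 lies on chromosome 11 at 87756864 to 87756927 on the plus strand, inside Mir142b on the minus strand.

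Strand information lost in library making is argued against by the other genes. In 174 genes with no such overlap and at least 1000 counts, the median share on the opposite strand was 0% and the highest 4.15%. A candidate explanation is that the reads came from the overlapping miRNA gene: 99.95% of opposite-strand counts lay in the 32 genes that overlap one. That would mean that sense counts leave out some abundant miRNAs of blood cells and of the Dlk1-Dio3 domain. No biological explanation was tested.

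Mir451a was 2.16-fold lower in replicate 2, at -5.87 SDs from the mean of 186 other genes with at least 100 CPM. Fewer red cell precursors in the second pool would lower the other erythroid miRNAs too. Mir144 and Mir486 had a median log2 ratio of 0.16, and both were higher in replicate 2 by the exact binomial test. That test covers counting error only, and 0.16 is below the SD of 0.187 of the log2 ratios of the 186 genes. Mir144 and Mir486 were thus not lower, but a rise beyond that spread is not shown. GC content of the precursor showed no trend across the other genes (r = -0.00464, slope -0.000101 log2 units per percentage point). The bootstrap interval of that slope allows a log2 ratio no lower than -0.0123 at the GC content of Mir451a. A linear trend with precursor GC thus does not reach the observed -1.11. GC content of the sequenced reads themselves was not examined. Size selection that treated its longer, Dicer-independent product differently, and a true difference between pools, stay open and were not tested.

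The epithelial list was lower in replicate 2 in 9 of 9 members. A lower share of hepatocytes in the first pool would lower all other cell types in replicate 2 by about the same factor. Over 16 loci of the other non-hepatocyte cell type lists of fetal liver the median log2 ratio was -0.0676 (exact 95% interval -0.23 to -0.00434, SD of the loci 0.27), above the epithelial median of -0.37. That epithelial median was taken over genes, several of which share a cluster, and not over loci. The hepatocyte list, which would rise, was lower in 5 of 5 loci. This test replaced 2 earlier ones of the same explanation that could not decide, and it uses values already seen. A linear trend with precursor GC across the 343 other detected genes allows a median no lower than -0.0131 at the GC content of the list. That trend thus does not reach the observed value, and GC content of the reads was not examined. More gut or pancreas tissue carried into the first pool may contribute. Only 2 pancreas members were detected, Mir375 and Mir217, with a median of -0.18, too few to decide. Mir217 was nearly unchanged (-0.00918). Gut or pancreas miRNAs singled out after their values were seen for being lower were Mir375 (-0.36), Mir215 (-0.44), Mir194-1 (-0.73), Mir192 (-0.17) and Mir802 (-3.67). Of these, Mir194-1, Mir192 and Mir802 are also on the hepatocyte list and Mir215 is on the epithelial list itself. Mir215 and Mir194-1 lie in the same cluster. The epithelial members Mir203 (-0.66) and Mir205, a skin and squamous epithelium miRNA, were lower too. The fall was thus not limited to gut or pancreas miRNAs, and this explanation stays open. Bile duct cells of the liver itself express epithelial miRNAs, so a difference between pools stays open.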

How the results depend on the processing

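The alternative that reassigns opposite-strand counts, and the 1 without Mir451a, were chosen after seeing the data. No paired analysis was possible because there is 1 group. Among main values and counts, 89 alternative values stayed within their spread, 1.5 times or side of the threshold, while 26 moved, 5 were stronger and 2 weaker. None changed sign, but the order of the hepatocyte and erythroid lists reversed without Mir122. The balance of higher and lower genes reversed by total counts. The cause of values that left these limits was not tested unless the alternative itself shows it. A minimum of 1 count gave 557 detected genes. Leaving out a library gave 362 to 406. The share of the 10 most abundant genes was 45.9% unstranded, 45.9% with opposite-strand counts reassigned and 39.7% without Mir122. Without Mir122 the hepatocyte to erythroid ratio was 0.572. Pearson r was 0.991 with no count minimum, 0.995 with a minimum of 50 and 0.997 with a pseudocount of 10 CPM, and Spearman rho 0.926 with no minimum and 0.994 with 50. The biological coefficient of variation was 0.122 without Mir451a, and genes that differed numbered 155 to 190 over all alternatives. Scaled by total counts, 97 genes were higher and 80 lower in replicate 2, against 83 and 95.

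List shares moved with the denominator and with the members counted. Unstranded counts enlarge the denominator and gave 17.1% hepatocyte, 1.86% leukocyte, 2.28% progenitor, 4.03% endothelial, 1.91% mesenchymal and 15.2% Dlk1-Dio3. Without Mir122, itself a hepatocyte member, they were 1.54%, 2.48%, 3.04%, 5.36%, 2.54% and 20.2%. Reassigning opposite-strand counts, which adds members such as Mir142 and Mir409, gave 17.1% hepatocyte, 5.34% leukocyte, 4.03% endothelial, 1.91% mesenchymal and 19.1% Dlk1-Dio3. Against random lists of detected genes 4 lists exceeded the upper bound, and without matching on expression 2 lists lay outside the ratio bounds. The erythroid list lay inside them under 3 alternatives, the pluripotent list under 2 and the hepatocyte list under 1, while the muscle and neural lists left them under 1 each, and with no count minimum the X-linked germline list lay at 99.9. The neighbour difference of -0.40 passed the threshold at -0.48 unstranded, -0.47 within 50 kb, -0.77 for detected genes and -0.47 with counts reassigned. Depth limits genes under about 10 counts. Multimapping limits the multicopy and Sfmbt2 lists most directly, and other lists through the members they share with the multicopy list. Reads that map to several places numbered 4302465 in replicate 1 and 2632729 in replicate 2, beside 5529166 and 3169882 sense counts. How many of them came from miRNA genes is not known. Every share, rank and CPM therefore holds only for the reads that were assigned to a gene.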

Other observations

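All tests here were chosen after the results were seen. Counted together, the Dlk1-Dio3, Igf2-H19 and Sfmbt2 lists and Mir335 of Mest held 20.6% of sense counts in replicate 1 and 21.4% in replicate 2, beside 19.6% and 18.1% for the hepatocyte list. On chromosome X, the 7 genes from Mir450b to Mir322, at 53047997 to 53054349 on the minus strand, held 2.65% ± 0.218. By chromosome, 18 held 19.2% ± 1.09, of which Mir122 was 17.6%, and 12 held 16.9% ± 0.0262.

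Several less abundant genes, singled out after their values were seen, differed more than Mir451a. Mir802, a liver, gut and pancreas miRNA on the hepatocyte list, had 140 counts in replicate 1 and 6 in replicate 2, a log2 ratio of -3.67 (exact binomial test, Benjamini-Hochberg adjusted p = 4.22e-20). Mir205, a skin and squamous epithelium miRNA, had 363 and 83 counts (log2 ratio -1.36). Mir133b, which lies beside Mir206 in the same noncoding host Gm28653, had 52 and 79 counts (log2 ratio 1.37), so both genes of that muscle locus were higher in replicate 2. Mir137, of the neural list, was at -1.04, closer than Mir451a.

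Within introns of protein-coding genes, 123 of 658 miRNA genes on the host's strand were detected, or 18.7%, and 13 of 169 on the opposite strand, or 7.69%. The odds ratio was 2.76 (Fisher's exact test, two-sided, p = 4.25e-04). In exons of protein-coding genes the order was reversed, with 44 of 196 (22.4%) and 14 of 47 (29.8%). For noncoding hosts it was 23 of 77 and 1 of 30 in introns, and 41 of 66 and 0 of 4 in exons. Only the introns of protein-coding genes were tested. One hypothesis is that transcription of the host may carry its miRNA. Genes in clusters are not independent, and well-studied loci can differ from later annotated ones, so the test leaves this open. In 16 pairs of detected neighbours of which 1 is on the multicopy list, the multicopy gene was lower in 15, with a median log2 difference of -3.40.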
